A study of Mus musculus with 9 samples.

How the data were processed

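Polyadenylated RNA was sequenced from intestinal epithelial cells of Lgr5-2A-eGFP mice aged 8 weeks, in which GFP reports the expression of Lgr5. Per the labels' protocols, crypts were released by chelation, digested to single cells with TrypLE and sorted on GFP by flow cytometry, with at least 30000 cells per fraction from the colon and 50000 from the small intestine. No other gate and no epithelial surface marker is named there. The 9 libraries form 3 groups of 3: colon GFP-high, colon GFP-negative and small intestine. The labels do not give the GFP fraction of the small intestinal libraries, so tissue and fraction could both differ between them and the colon groups. They do not say whether the libraries come from separate animals, so the p-values measure the spread between these samples. All 9 library names in the table were matched to the labels, and every library kept the group its label gives.

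Per the submitters' processing notes, STAR, featureCounts, Subread and edgeR were used with genome build mm10, with no versions given. The deposited table holds, per the file headers, the raw read count of each of 78239 genes in each library. It also holds the deposited log2 CPM, log2 RPKM and log2 TPM, a gene length and, per library, a total and a TMM factor, which is a ratio between 0.805 and 1.21. Recomputing the log2 CPM, the log2 RPKM (prior count 2) and the factors from the counts with edgeR gave the deposited values within 1e-06, and log2 TPM differed from log2 RPKM by a constant per library. Only the counts entered the tests. The strand setting, the handling of reads that map to several places and the annotation release are not given in the sources used here. Near-identical genes such as the defensins, and genes that overlap others, are therefore uncertain as single genes.

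Of the gene IDs in the table, 51498 (65.8%) were found in GENCODE M21, and 35 of those (0.068%) carried the same version there. IDs and symbols are printed as the table gives them. Coordinates are those of GENCODE M21 on GRCm38, and the counts may rest on another annotation. A total of 312 symbols were carried by more than 1 ID (629 genes), and the tests ran by ID.

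Differential expression was tested in R 4.3.3 with edgeR 4.0.16 on the raw counts. Genes were filtered with filterByExpr by group, which left 20610 genes tested and 57629 not tested, and libraries were scaled by TMM. A single fit of all 9 libraries (glmQLFit) gave all contrasts by the two-sided quasi-likelihood test (glmQLFTest), with Benjamini-Hochberg adjustment over the genes tested. A gene was called where its adjusted p was under 0.05. The comparisons were colon GFP-high against colon GFP-negative, colon GFP-high against small intestine and, as a secondary comparison reported by counts, lists and study genes only, small intestine against colon GFP-negative. Genes higher in colon GFP-high than in both other groups were counted as the intersection of the first 2 contrasts. Levels are CPM on TMM-scaled library sizes, given as mean ± SD with n = 3 libraries per group. Log2 fold changes carry a standard error taken from the fold change and its quasi-likelihood F statistic. A fold against a group with no counts is given as at least its value against 3 counts per library, and with 1 to 3 counts as a ratio with a 95% counting interval. These intervals and floors cover counting error only.

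Counts per library lay between 86621513 and 106673547, at which 3 counts make 0.0233 to 0.0412 CPM on the TMM-scaled sizes. The common biological coefficient of variation was 0.726, so the spread between libraries and not the depth set the precision. The counts of replicates differed by a chi-square per gene of 501.6 to 1233.2 between pairs of libraries of a group. The fit was tested for each comparison on simulated counts, with 100 genes changed by each fold. The counts had the means, library sizes and spread between libraries of these data. That spread was estimated with all libraries as labelled, including the colon replicate 2 pair whose labels Lgr5 goes against. The changed genes were drawn from those with a mean of at least 5 CPM. The fit called 25% of genes changed 4-fold and 90% of those changed 16-fold for colon GFP-high against colon GFP-negative (19684 genes, 6 unchanged genes called). For colon GFP-high against small intestine it called 36% and 89% (19715 genes, 2 unchanged called), and for small intestine against colon GFP-negative 46% and 94% (19722 genes, 5 unchanged called). In the simulation a raised list had a camera p of 5.35e-17 and an unchanged list one of 0.76. The simulated genes were drawn independently of each other. Between the colon fractions the estimated correlation was 0.055 in the posterior Hox, 0.82 in the mitosis and 0.883 in the immune cell list. The simulation therefore does not show how camera behaves on lists with such correlated genes.

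The comparisons, 34 gene lists, rule for named genes and alternative analyses other than those named below were chosen before the data were examined. The lists were the study genes, intestinal stem cell, Wnt target, mitosis, DNA replication, ribosome biogenesis, colonocyte, small intestinal enterocyte, goblet cell, deep crypt secretory cell, Paneth cell, enteroendocrine cell, tuft cell, posterior Hox, anterior and middle Hox, gut regional regulator, NADPH oxidase, neuropeptide Y family, Notch pathway, BMP response, EGF receptor pathway, MHC class II, mucosal defence, fatty acid oxidation, cholesterol synthesis, regeneration, immediate early, immune cell, stromal cell, endothelial cell, enteric glia and neuron, red blood cell, sex-linked and mitochondrial RNA lists. Muc3 was missing from the table. The lists share some genes. Each list was tested with camera of limma 3.58.1 (preset correlation 0.01, adjusted over the 34 lists), which compares it with all other genes, and again with an estimated correlation. The fry test, which asks whether the genes of a list move one way on balance, was run beside it. Members past the threshold were counted with p adjusted over all genes and adjusted over the list alone.

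Named genes are the 3 study genes and, for the first 2 comparisons, the 6 called genes with the largest change in each direction among those with a mean of at least 10 CPM in the higher group and ranges that do not overlap. Symbols starting with Gm and a digit or ending in Rik were left out. From each list the 2 called members with the largest change and at least 5 CPM were added, or, with no call, the member with the highest mean CPM over all 9 libraries. Members of lists with 5 or fewer calls and genes of the fits without the pair of colon replicate 2 libraries were chosen after their values were seen. A few genes that this rule or the lists would name are not reported here. For the intersection the rule took the 8 largest genes, and for the secondary comparison the study genes.

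The alternatives chosen beforehand were RLE, upper quartile and total-count scaling, DESeq2 1.42.0, limma-voom, no filter beyond 1 count, a filter at 1 CPM in at least 3 libraries, only the 2 groups compared, the replicate number or the start of the library name tag as a block, each library left out in turn, mitochondrial genes left out and a threshold of 0.01. Tags that differ only in their last part shared a block. Below, the library name tag as a block means this grouping by the start of the tag. These blocks are unbalanced, since 1 holds no small intestinal library and 1 no colon GFP-negative library. A fall in calls with this block may come from the overlap of tag and group. Because Lgr5 went against the labels of the colon replicate 2 libraries, fits without that pair of libraries in edgeR, DESeq2 and limma-voom were added after seeing the data. For single genes, the alternatives given below leave out the fit of only the 2 groups compared and the threshold of 0.01. Upper quartile scaling moved the median log2 fold change of all genes by 0.20 for colon GFP-high against small intestine and by -0.125 for small intestine against colon GFP-negative. Total-count scaling moved it by 0.14 for colon GFP-high against colon GFP-negative. No alternative scaling moved the share of calls in each direction by more than 10 percentage points. No sample was left out of the fits in edgeR that give the comparisons, and the fits without the pair are named as such wherever they are given.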

Results

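Transcripts were counted in 9 libraries of sorted intestinal cells from mice that carry GFP as a reporter of Lgr5, a receptor found on intestinal stem cells. The groups were colon GFP-high, colon GFP-negative and small intestine, with 3 libraries each. The libraries held 90841832, 106193616 and 93063685 counts in colon GFP-high replicates 1 to 3, 86621513, 100844799 and 95533366 in colon GFP-negative and 90613900, 99390274 and 106673547 in small intestine. Between 20715 and 28206 genes had at least 1 count in a library, and mitochondrial genes took 0.678% to 1.26% of the counts. On the first principal component, which held 49.0% of the variance, the small intestinal libraries lay at positive values up to 135 and the colon libraries between -145 and -9.52. The series title names Nox1, which encodes a superoxide-generating NADPH oxidase, and Npy1r, which encodes a receptor for neuropeptide Y and peptide YY, as regional markers of colon stem cells.

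The reporter's own gene went against the labels in 1 pair of colon libraries. Lgr5 (ENSMUSG00000020140.16, chromosome 10, 115450311 to 115587780, minus strand) stood at 43.9 and 72.6 CPM in colon GFP-high replicates 1 and 3 and at 2.83 and 6.37 CPM in colon GFP-negative replicates 1 and 3. The library labelled colon GFP-high replicate 2 had 0.954 CPM, the lowest of the 9 libraries, and the library labelled colon GFP-negative replicate 2 had 61.6 CPM. Small intestinal replicates 1 to 3 had 58.1, 120 and 209 CPM. Nox1 (ENSMUSG00000031257.15, chromosome X, 134086421 to 134221956, minus strand) had 50.5, 16.9 and 74.0 CPM in colon GFP-high, 34.1, 117 and 9.96 CPM in colon GFP-negative and 5.84, 14.6 and 7.83 CPM in small intestine. Npy1r (ENSMUSG00000036437.7, chromosome 8, 66697192 to 66706792, plus strand) had 10.4, 19.7 and 17.9 CPM in colon GFP-high and 13.2, 16.8 and 5.20 CPM in colon GFP-negative. In small intestine Npy1r had 0.193, 0.117 and 0 CPM, where 3 counts would make 0.0233 CPM in replicate 3. Every direction given for a colon fraction rests on labels that Lgr5 goes against in this pair of libraries.

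**Figure D1:**
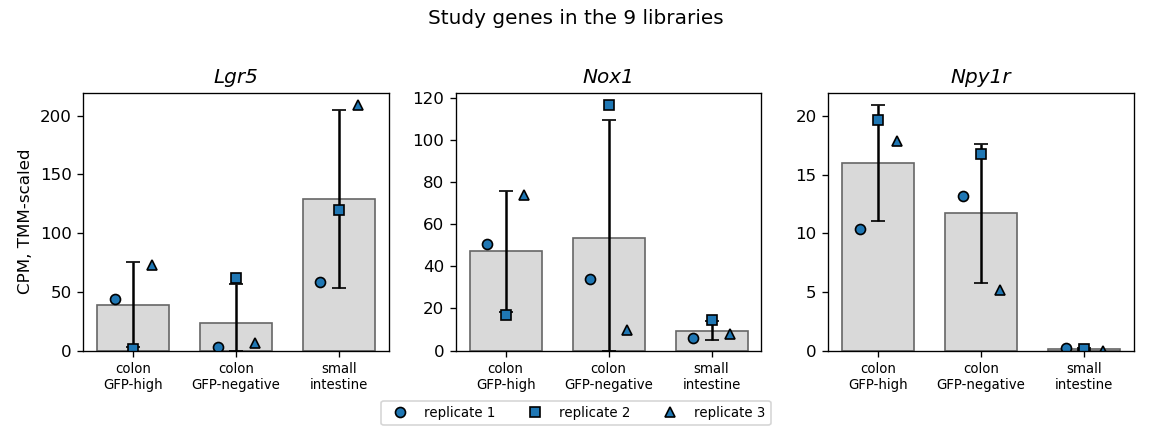
CPM of Lgr5, Nox1 and Npy1r on linear axes in the 3 groups; bars are means of 3 libraries, error bars SD and points single libraries marked by replicate. Lgr5 was 0.954 CPM in the library labelled colon GFP-high replicate 2 and 61.6 CPM in the one labelled colon GFP-negative replicate 2, and Npy1r was at or below 0.193 CPM in small intestine.

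Reporter-high and reporter-negative cells of the colon were compared to ask which genes go with the stem-cell reporter. With the libraries as labelled, Lgr5 was 39.2 ± 36.1 CPM (SD, n = 3) in GFP-high and 23.6 ± 33.0 CPM in GFP-negative cells, a log2 fold change of 0.73 ± 1.36 (SE) that turned to -0.08 without colon GFP-high replicate 3 and to -0.73 with the library name tag as a block. Nox1 was 47.1 ± 28.7 and 53.5 ± 55.9 CPM (log2 fold change -0.18 ± 0.82). Its sign turned without the library labelled colon GFP-negative replicate 2 (1.10) or colon GFP-high replicate 2, in limma-voom and with total-count scaling. Npy1r was 16.0 ± 4.93 and 11.7 ± 5.94 CPM (0.45 ± 0.89). All of these differences lay within the spread between replicates (adjusted p = 1 in edgeR). No gene was called among the 20610 tested in edgeR, with 226 (1.10%) at an unadjusted p under 0.05. That is less than the share of 0.05 that no difference would give, so these 226 are no sign of one. DESeq2 called 1 gene, lower in GFP-high (406 at an unadjusted p under 0.05), and limma-voom 0 (226). The gene called by DESeq2, Pitx1, chosen after its values were seen, had 2.01 CPM in the library labelled colon GFP-negative replicate 2 and 0 in the other 5 colon libraries.

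Without the pair of colon replicate 2 libraries, a setting chosen after seeing the data, DESeq2 called 4 of 30 stem cell genes higher and 2 lower in GFP-high cells. It called 700 genes, 119 higher and 581 lower in GFP-high cells (n = 2 per colon group), while edgeR called 0 (1582 at an unadjusted p under 0.05) and limma-voom 2 (1840), the lower Lyz2 and Pcsk1n. Lgr5 had a log2 fold change of 3.62 ± 0.69 (SE) in DESeq2 there (adjusted p = 1.96e-05, the lowest of its 22 alternatives, which ran to 1). Its values were the reason for leaving the pair out, so this is no separate test. Nox1 was not called there, with 1.497 in edgeR, 1.46 in DESeq2 and 1.75 in limma-voom (adjusted p = 0.703, 0.405 and 0.563, and up to 1 over its alternatives). The genes that follow were chosen after their values were seen. Of 30 stem-cell genes DESeq2 called 4 higher, namely Lgr5, Smoc2 (log2 fold change 3.10 ± 0.59), Ascl2 (2.79 ± 0.63), a transcription factor of stem cells, and Axin2 (2.27 ± 0.52), a Wnt target, and 2 lower, Aqp4 and Slc14a1. Smoc2 stood at 305 and 433 CPM in GFP-high replicates 1 and 3, at 54.6 and 28.7 CPM in GFP-negative replicates 1 and 3, and at 32.1 and 417 CPM in the replicate 2 libraries labelled GFP-high and GFP-negative. Of 25 enteroendocrine genes 7 were lower in GFP-high cells, among them Chga (log2 fold change -4.36 ± 0.56) and Tph1 (-5.24 ± 0.70). So were 16 of 19 immune cell genes and all 7 MHC class II genes, each of which was higher in colon GFP-negative replicate 3 than in replicate 1. Cd74 was 4718 CPM in that replicate 3 against 126 CPM in replicate 1 and 54.5 and 52.8 CPM in GFP-high replicates 1 and 3, and H2-Aa was 1111 against 35.1 CPM in replicate 1. All of these calls came from DESeq2 alone, except that limma-voom also called Lyz2.

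**Figure D2:**
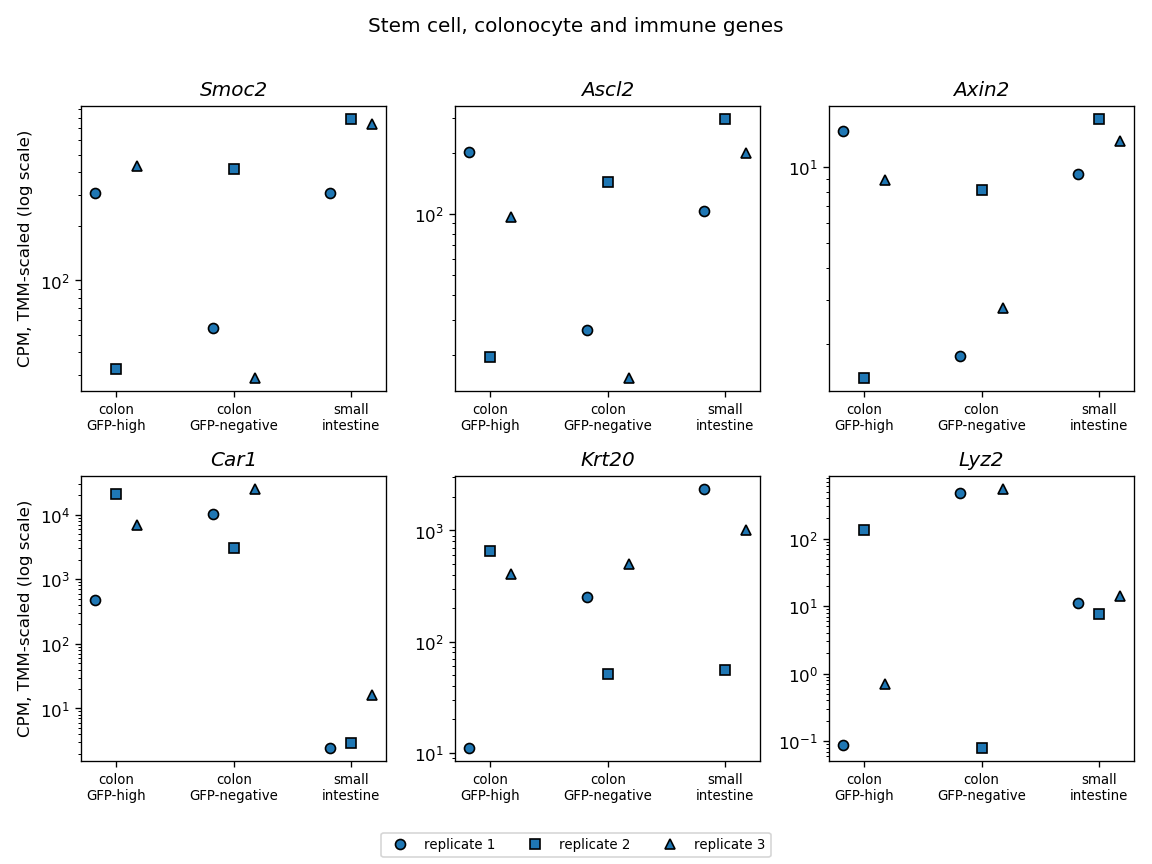
CPM of Smoc2, Ascl2, Axin2, Car1, Krt20 and Lyz2 on log axes in each library, with points marked by replicate. Smoc2 was 32.1 CPM in the library labelled colon GFP-high replicate 2 and 417 CPM in the one labelled colon GFP-negative replicate 2.

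Of the 34 gene lists, none held a gene called between the colon fractions with all libraries in edgeR; adjusted over the list alone 1 gene passed, a gut regional regulator higher in GFP-high. Against all other genes, camera placed 4 lists higher in GFP-high: the intestinal stem cell list (25 of 30 estimates positive, median log2 fold change 0.39, adjusted p = 0.025), the Wnt target list (18 of 20, 0.55, adjusted p = 0.0312), the tuft cell list (15 of 16, 1.37, adjusted p = 2.27e-07) and the anterior and middle Hox list (13 of 14, 0.62, adjusted p = 0.00161). It placed 4 lists lower: colonocyte (22 of 27 estimates negative, median -0.26, adjusted p = 0.00297), goblet cell (16 of 18, -0.42, adjusted p = 0.006), Paneth cell (17 of 21, -0.32, adjusted p = 0.0162) and immune cell (19 of 19, -2.93, adjusted p = 0.000275). All 8 calls were lost with an estimated correlation (adjusted p = 0.91 for each with an estimated correlation), and fry gave an adjusted p of 0.948 for each. Without the pair of colon replicate 2 libraries the tuft cell call was lost (camera adjusted p = 0.142) and 7 of the 8 stayed. Camera then called 16 lists, none of them with an estimated correlation (adjusted p = 0.452 or more with an estimated correlation). The stem cell list had 14 genes higher and 2 lower adjusted over the list alone in edgeR. For some of these lists 1 library was the highest of its group for most genes. All 19 immune cell genes and all 7 MHC class II genes were highest in colon GFP-negative replicate 3 of the GFP-negative libraries, where Lyz2, the lysozyme of macrophages and neutrophils, was 548 CPM against 472 and 0.0792 CPM. The tuft cell genes were highest of the GFP-high libraries in replicate 3 for 11 of 16. Immune transcripts were not confined to 1 colon library. The library labelled colon GFP-high replicate 2 was highest of its group for 18 of 19 immune cell and all 7 MHC class II genes. Lyz2 was 133 CPM there, against 0.0868 and 0.713 CPM in GFP-high replicates 1 and 3. Of 27 colonocyte genes 21 were highest of the GFP-negative libraries in replicate 3. In the library labelled GFP-negative replicate 2, 24 of 30 stem cell and 16 of 20 Wnt target genes were highest of the group.

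The members of each list with the highest mean CPM over all 9 libraries, none of them called, had log2 fold changes (± SE) for GFP-high over GFP-negative as follows. The small intestinal libraries entered that mean. Olfm4 was chosen through its level there and is not the most abundant stem cell gene of the colon libraries. Among growth genes Myc had 0.55 ± 0.52, Ube2c of the mitosis list -0.01 ± 0.45, Mcm6 of the DNA replication list 0.11 ± 0.62 and Ncl of the ribosome biogenesis list -0.03 ± 0.76. Among genes of mature cells Car1, a carbonic anhydrase of colonocytes, had -0.43 ± 1.25, Apoa1 -1.89 ± 1.55, Agr2 -0.15 ± 0.69, Mptx1 -0.41 ± 1.06, Lyz1 -1.33 ± 1.26 and Chga, a granin of enteroendocrine cells, 0.99 ± 1.68. Chga stood at 4295 CPM in the library labelled colon GFP-high replicate 2 and at 28.8 and 81.7 CPM in the other 2 GFP-high libraries. Among regional and signalling genes Hoxb13 had -0.53 ± 0.42, Hoxa7 -0.07 ± 0.59, Cdx1 0.18 ± 0.37, Rac1 of the NADPH oxidase list -0.30 ± 0.26, Pyy of the neuropeptide Y family 0.75 ± 1.58, Olfm4 of the stem cell and Notch lists -0.36 ± 0.40, Id1 of the BMP response list -0.55 ± 0.47 and Lrig1 of the EGF receptor list 0.19 ± 0.64. Among defence and metabolic genes Cd74 of MHC class II had -3.25 ± 1.69, Pigr -0.66 ± 0.55, Fdps of cholesterol synthesis 0.00 ± 0.34, Krt7 of the regeneration list 0.23 ± 0.35 and Ier2 of the immediate early list 0.57 ± 0.40. Markers of other cells and controls had -2.93 ± 2.43 (Lyz2), 0.09 ± 0.51 (Pdgfrb, stromal cells), 1.21 ± 0.53 (Esam, endothelial cells), -1.87 ± 1.47 (Hba-a1, red blood cells), -0.04 ± 0.22 (Eif2s3y, Y-linked) and -0.10 ± 0.43 (mt-Cytb). The signs of Ube2c, Ncl, Hoxa7, Eif2s3y, mt-Cytb and Fdps turned under at least 1 alternative scaling. Leaving out 1 library turned the signs of 20 of these 29 genes, among them Chga (to -3.74) and Cd74 (to 1.22, without colon GFP-negative replicate 3). The signs of Myc, Lyz1, Hoxb13, Rac1, Id1, Pigr, Ier2, Lyz2 and Esam held without each library in turn. Their sizes moved, with Lyz1 between -3.92 and -0.24 and Lyz2 between -9.72 and -2.36. Median, mean and camera direction differed in sign for 7 uncalled lists, namely NADPH oxidase, mucosal defence, regeneration, immediate early, stromal cell, red blood cell and sex-linked.

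Colon GFP-high cells were compared with small intestinal cells to ask what sets reporter-high cells of the colon apart by region, with the GFP fraction of the small intestinal libraries not given in the labels. The colon cells carried posterior Hox genes, which pattern the hindgut, that were close to absent in small intestine. Hoxb13 was 301 ± 107 CPM (SD, n = 3) in colon GFP-high and 0.314 ± 0.0297 CPM in small intestine, 958-fold higher (log2 fold change 9.90 ± 0.61 SE, adjusted p = 0.000106 in edgeR). Small intestinal cells carried 2706-fold more Olfm4, a stem-cell marker of the small intestine, at 7055 ± 1980 CPM against 2.61 ± 0.325 CPM (log2 fold change -11.40 ± 0.61, adjusted p = 7.46e-05). They also carried the antimicrobial defensins of Paneth cells, which colon GFP-high cells had at or near 0. Npy1r was 160-fold higher in the colon cells, at 16.0 ± 4.93 against 0.103 ± 0.0970 CPM (log2 fold change 7.32 ± 1.19, adjusted p = 0.00962; 8.12 without small intestine replicate 1 and 6.70 without replicate 3).

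In edgeR 1173 of 20610 genes were called, 813 higher and 360 lower in colon GFP-high cells, 1161 of them by a log2 fold change of more than 1. DESeq2 called 2713 (1169 of them among the 1173) and limma-voom 1060 (930 of them among the 1173). The count fell to 508 without the pair of colon replicate 2 libraries (486 of them among the 1173) and to 437 with the library name tag as a block (428 of them among the 1173). It was also more than 1.5 times lower without colon GFP-high replicate 1 (705), 2 (564) or 3 (666), colon GFP-negative replicate 1 (683), or small intestine replicate 1 (635) or 3 (566). Of 39 named genes called, 23 were called without each library in turn and 18 in every alternative.

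Npy1r was higher in all 3 colon GFP-high libraries than in any small intestinal library. It was called in all 22 alternatives checked for single genes (adjusted p from 6.59e-17 to 0.0486). Nox1 was 47.1 ± 28.7 CPM in colon GFP-high and 9.41 ± 4.57 CPM in small intestine, with a log2 fold change of 2.32 ± 0.87 that did not pass in edgeR (adjusted p = 0.174). It was called by DESeq2 (adjusted p = 0.023, from 0.000376 to 0.417 over its alternatives). Lgr5 was 39.2 ± 36.1 CPM and 129 ± 75.9 CPM (log2 fold change -1.72 ± 1.39, adjusted p = 0.553), within the spread between replicates. With single libraries left out its log2 fold change ran from -2.49 to -1.15. Of these study genes 1 was called, and 2, Npy1r and Nox1, adjusted over the list alone; the camera test of the list gave an adjusted p of 0.288.

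Among the 6 largest increases in colon GFP-high cells by the naming rule were Best2, a bestrophin anion channel (1957-fold, log2 fold change 10.94 ± 1.29), Lpo, which encodes lactoperoxidase (1764-fold, 10.78 ± 0.52), Ccn3 (1599-fold, 10.64 ± 0.63) and Nxpe4 (1596-fold, 10.64 ± 0.81), with adjusted p from 7.46e-05 to 0.00264. Insl5, ranked second, is given with the enteroendocrine genes. The log2 fold change of Best2 was 9.79 without colon GFP-high replicate 2, and that of Nxpe4 11.53 and 9.94 without small intestine replicates 2 and 3. Ccn3 stood at 511 ± 272 CPM against 0.317 ± 0.0347 CPM. Cma1, which encodes a chymase, was 10.6 ± 6.67 CPM in colon GFP-high with 2 counts in the small intestinal libraries, a ratio of 1610 (446 to 13300; adjusted p = 0.00238) that was 1070 without small intestine replicate 2 and at least 300 without replicate 3, which held both counts. Best2 and Cma1 were not called by limma-voom (adjusted p = 0.173 and 0.114, the highest of their alternatives, which began at 4.21e-35 and 3.25e-15). In small intestine Defa40 was at least 1090-fold higher (adjusted p = 0.0016), with 32.5 ± 12.1 CPM against no count in colon GFP-high. Defa26 had a ratio of 8000 (2210 to 66000; adjusted p = 0.000869) that was 5270 without colon GFP-high replicate 1 and at least 1710 without replicate 3. Enpp7, an intestinal sphingomyelinase, was 7619-fold higher (log2 fold change -12.90 ± 2.00, adjusted p = 0.00815; -11.92 without small intestine replicate 1). Enpp7 was past the threshold without each library in turn but missed it in 4 other alternatives (adjusted p up to 0.574, from 2.14e-11). The single defensin genes are uncertain, since reads could be split among near-identical copies.

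Among genes of regional identity, all 11 posterior Hox genes tested were higher in colon GFP-high cells, with a median log2 fold change of 9.51, or 6.54 with the 5 genes without counts in small intestine at their bound (camera adjusted p = 1.75e-13). Hoxd13 was at least 190-fold higher (adjusted p = 0.00215). Of the 34 lists this was the only one whose call held with an estimated correlation (adjusted p = 0.0227 with an estimated correlation). By fry it held too (adjusted p = 7.04e-05), as did Paneth cell (0.000245), anterior and middle Hox (0.000562) and gut regional regulator (0.00508). So did neuropeptide Y family (0.00508), goblet cell (0.00588), deep crypt secretory (0.0184) and regeneration (0.0278). Notch passed by fry (0.00423) but not by camera. The other 9 lists called by camera did not pass by fry (adjusted p = 0.0519 to 0.573). Of 14 anterior and middle Hox genes 7 were higher and 7 did not pass, with 2 higher without the pair of colon replicate 2 libraries (11 higher adjusted over the list alone; camera adjusted p = 3.24e-10, and adjusted p = 0.0662 with an estimated correlation). Hoxa7 was 48.6-fold (log2 fold change 5.60 ± 0.72, adjusted p = 0.00359) and Hoxa5 19.9-fold higher (4.31 ± 0.65, adjusted p = 0.00685), with 6.53 and 5.12 without small intestine replicate 3. Among 15 gut regional regulators 4 were lower in colon GFP-high cells (2 without the pair of colon replicate 2 libraries), 1 was higher and 10 did not pass (9 lower and 1 higher adjusted over the list alone; camera down, adjusted p = 0.00361, and adjusted p = 0.182 with an estimated correlation). Gata4, a transcription factor of the proximal small intestine, was 453-fold lower (log2 fold change -8.82 ± 1.09, adjusted p = 0.00302) and Onecut2 319-fold lower (-8.32 ± 0.77, adjusted p = 0.00264), with -9.46 and -8.99 without the library labelled colon GFP-high replicate 2. Hnf4g and Hnf4a were the other 2 lower ones, both chosen after their values were seen.

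**Figure D3:**
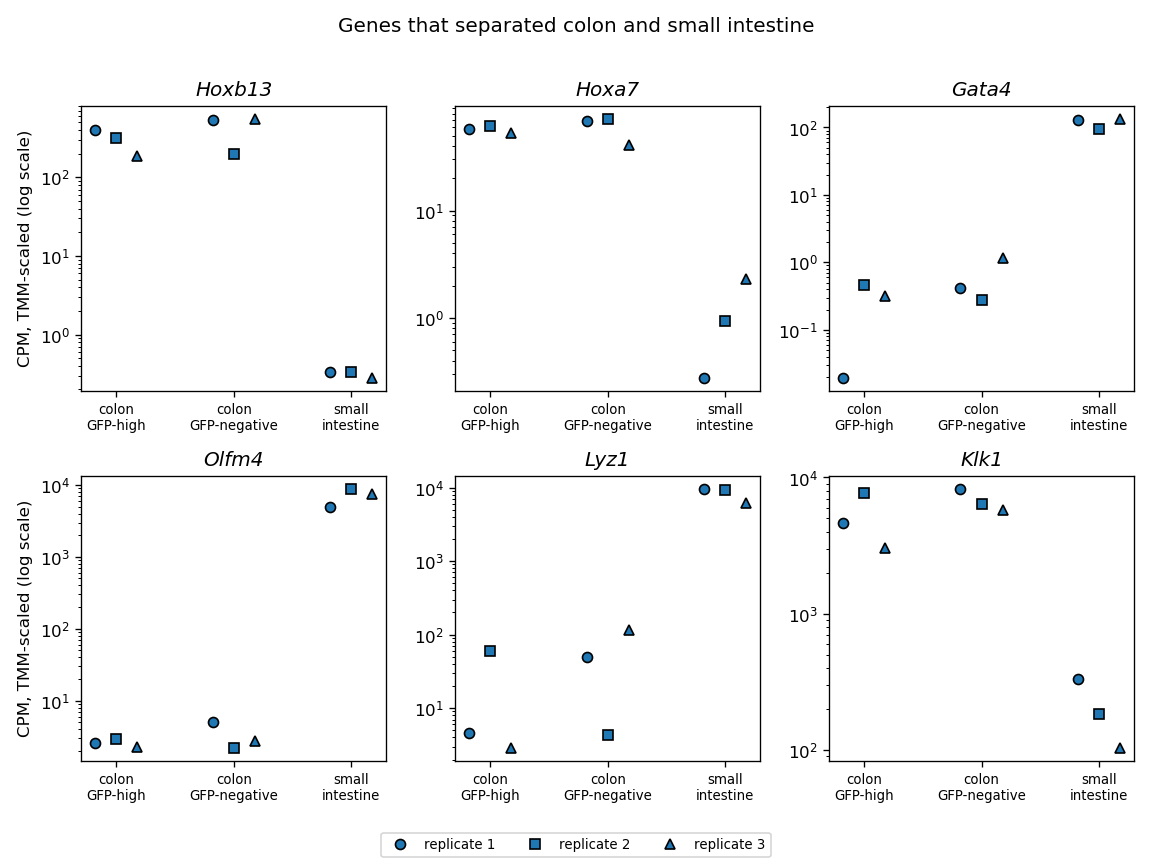
CPM of Hoxb13, Hoxa7, Gata4, Olfm4, Lyz1 and Klk1 on log axes in each library, with points marked by replicate. Hoxb13 was 187 to 400 CPM in colon GFP-high and 0.279 to 0.331 CPM in small intestine, and Olfm4 2.28 to 2.93 and 4923 to 8836 CPM.

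Of 21 Paneth cell genes 13 were lower in colon GFP-high cells and 1, Nupr1 (chosen after its values were seen), was higher (17 and 1 adjusted over the list alone; camera down, adjusted p = 4.79e-18, and adjusted p = 0.0662 with an estimated correlation). Defa20 was 4361-fold lower (log2 fold change -12.09 ± 1.43, adjusted p = 0.00267; 6.77e-33 to 0.0942 over its alternatives), with -10.90 without small intestine replicate 2. Of 18 goblet cell genes 9 were higher, 9 did not pass and 13 were higher adjusted over the list alone (camera adjusted p = 3.24e-10, and adjusted p = 0.253 with an estimated correlation). In the library labelled colon GFP-high replicate 2 stood the highest GFP-high value of 15 of the 18, and 7 were called without the pair of colon replicate 2 libraries (mean log2 fold change 1.64 against 2.63). Klk1, a kallikrein, was 24.8-fold higher (log2 fold change 4.63 ± 0.59, adjusted p = 0.00352). Retnlb, a goblet cell antimicrobial protein, had a log2 fold change of 9.72 ± 1.70 (adjusted p = 0.0132) that lost its call without small intestine replicate 1, 2 or 3 (adjusted p from 0.0505 to 0.0694, the highest of its alternatives, which began at 2.81e-19). Without the library labelled colon GFP-high replicate 2 it was 7.21. Of 8 deep crypt secretory genes 3 were higher, namely Mptx1 (1011-fold, log2 fold change 9.98 ± 1.56, adjusted p = 0.00832), Retnlb and Kit, and Dll1 was lower. Mptx1 had 44240 CPM in the library labelled colon GFP-high replicate 2 against 2223 and 2852 CPM, and a log2 fold change of 7.29 without that library. Its call was lost with the replicate number as a block (adjusted p = 0.0547, the highest of its alternatives, which began at 4.2e-63). In this list 6 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000419, and adjusted p = 0.292 with an estimated correlation). Of 30 stem cell genes 4 were lower and 26 did not pass (5 lower adjusted over the list alone; camera adjusted p = 4.35e-06, and adjusted p = 0.564 with an estimated correlation). All 30 were lowest of the small intestinal libraries in replicate 1, and 23 were lowest of the GFP-high libraries in the one labelled replicate 2. The 4 lower genes were Olfm4, Gkn3 (1275-fold, log2 fold change -10.32 ± 1.05, adjusted p = 0.00138) and, chosen after their values were seen, Slc14a1 and Igfbp4.

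Several absorptive and endocrine genes were called close to the threshold, with calls that were lost without 1 library while the folds stayed in the same direction. Of 25 small intestinal enterocyte genes 15 were lower in colon GFP-high cells and 10 did not pass (22 lower adjusted over the list alone; camera adjusted p = 3.18e-10, and adjusted p = 0.469 with an estimated correlation), and 2 were called without the pair of colon replicate 2 libraries. Its named members Apoa4 (log2 fold change -10.69, adjusted p = 0.0233) and Lct, which encodes lactase (-9.95, adjusted p = 0.0404), both lost their calls without any 1 of the 3 colon GFP-high libraries or small intestine replicate 1 or 3. Lct also lost it without colon GFP-negative replicate 1 or 2. The adjusted p was then 0.0524 to 0.104 for Apoa4 and 0.0511 to 0.129 for Lct. Their log2 fold changes ran from -11.43 (without colon GFP-high replicate 1) to -9.17 (without small intestine replicate 1) for Apoa4. Those of Lct were -9.35 and -10.93 without colon GFP-high replicates 1 and 2 and -8.96 without small intestine replicate 1. Of the small intestinal libraries, replicate 1 was highest for all 25 genes and replicate 2 lowest for 23, with Apoa4 at 12.9 CPM. Of 27 colonocyte genes 5 were higher and 22 did not pass (8 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0154, and adjusted p = 0.798 with an estimated correlation). The list call was lost without that pair (camera adjusted p = 0.0667, median log2 fold change 0.78 against 1.22), and 16 of the 27 were highest of the GFP-high libraries in the one labelled replicate 2. Car1 was 9423 ± 10500 CPM against 7.22 ± 7.82 CPM (log2 fold change 10.35 ± 1.85, adjusted p = 0.0146) and lost its call without small intestine replicate 1 or 2 (adjusted p = 0.0555 to 0.0635). Slc6a14, an amino acid transporter (8.58 ± 1.43, adjusted p = 0.0105), lost it without small intestine replicate 3 (adjusted p = 0.0586). Car1 was 10.94, 8.98 and 11.75 without colon GFP-high replicates 1 and 2 and small intestine replicate 3. Slc6a14 was 7.86 without colon GFP-high replicate 2. Sult1a1 and Scnn1b, chosen after their values were seen, were also among the 5. Of 25 enteroendocrine genes 1 was higher, 2 lower and 22 not past (the same numbers adjusted over the list alone; camera adjusted p = 0.569). Insl5, a hormone of colonic L cells (log2 fold change 10.90 ± 2.51, adjusted p = 0.0405), lost its call without any library but colon GFP-negative replicates 1 and 3 (adjusted p = 0.0558 to 0.157). It was 9.96 without colon GFP-high replicate 2. Gip, a hormone of the small intestine (-9.35 ± 2.10, adjusted p = 0.0369), lost it without any library but colon GFP-negative replicate 3 and small intestine replicate 2 (adjusted p = 0.0521 to 0.139). It was -11.42 without colon GFP-high replicate 1 and -5.77 without small intestine replicate 1. Ghrl was the other lower gene, chosen after its values were seen. Without the pair of colon replicate 2 libraries no enteroendocrine gene was called. The adjusted p of these genes reached 0.304 (Apoa4), 0.597 (Lct), 0.0635 (Car1), 0.188 (Slc6a14), 0.36 (Insl5) and 0.459 (Gip) over their alternatives.

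Among the largest decreases 3 more lost their calls without 1 library. Sult6b2 was at least 930-fold (adjusted p = 0.0192) and G6pc1, a glucose-6-phosphatase, at least 666-fold lower in colon GFP-high cells (adjusted p = 0.0303). Both lost their calls without any 1 of the 3 colon GFP-high libraries or small intestine replicate 1 or 3, and G6pc1 also without colon GFP-negative replicate 1 (adjusted p = 0.0515 to 0.0607 for Sult6b2 and 0.065 to 0.0807 for G6pc1). Without small intestine replicate 1 they were at least 478-fold and at least 253-fold lower. Defa32, with 1 count in colon GFP-high and a ratio of 18900 (3390 to 746000; adjusted p = 0.00833), lost its call without the library labelled colon GFP-high replicate 2 (adjusted p = 0.0562), which held that count, and was then at least 2190-fold lower. Its ratio was 12400 and 12200 without colon GFP-high replicates 1 and 3 and 7250 without small intestine replicate 2. Over their alternatives the adjusted p ran up to 0.453 (Sult6b2), 0.475 (G6pc1) and 0.541 (Defa32).

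Signalling lists held few calls. Tuft cell genes had 1 of 16 higher, Gnat3, a taste receptor G protein (24.8-fold, log2 fold change 4.63 ± 0.77, adjusted p = 0.0105; camera adjusted p = 0.413), which lost its call without small intestine replicate 1 or 3 (adjusted p = 0.0509 to 0.0622; up to 0.0815 over its alternatives). Of 12 Notch pathway genes 3 were lower (camera adjusted p = 0.0576), namely Olfm4, Dll1 (log2 fold change -1.65 ± 0.35, adjusted p = 0.0278) and, chosen after its values were seen, Notch2. Dll1 lost its call without colon GFP-high replicate 1 or 3, colon GFP-negative replicate 1 or small intestine replicate 2 or 3 (adjusted p = 0.0519 to 0.0969, the highest over its alternatives). Of 16 EGF receptor genes 1 was higher, Etv5 (2.52 ± 0.61, adjusted p = 0.0489), and 1 lower, Erbb3 (-1.16 ± 0.26, adjusted p = 0.0386; camera adjusted p = 0.513). Etv5 lost its call without any library but colon GFP-negative replicate 3 (adjusted p = 0.0512 to 0.13; up to 0.136 over its alternatives), and Erbb3 without any but colon GFP-negative replicate 3 and small intestine replicate 2 (0.0521 to 0.149; up to 0.206). Without the pair of colon replicate 2 libraries neither this list nor the cholesterol synthesis list had a call. Neuropeptide Y family genes had 1 of 4 higher, Npy1r (2 adjusted over the list alone; camera adjusted p = 0.027, and adjusted p = 0.253 with an estimated correlation). None of 20 Wnt target genes (camera adjusted p = 0.252), 10 BMP response genes (0.498) or 10 NADPH oxidase genes (0.065) passed, adjusted over all genes or over the list alone; Myc had a log2 fold change of -0.83 ± 0.52, Id1 0.59 ± 0.47 and Rac1 0.04 ± 0.26.

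Metabolic, defence and repair genes had calls in both directions. Of 12 fatty acid oxidation genes 1 was higher and 1, Etfdh, was lower (log2 fold change -1.01 ± 0.24, adjusted p = 0.0433), with 1 higher and 3 lower adjusted over the list alone (camera down, adjusted p = 0.0284, and adjusted p = 0.646 with an estimated correlation). Etfdh lost its call without any 1 of the 9 libraries (adjusted p = 0.0536 to 0.149; up to 0.156 over its alternatives). Of 16 cholesterol synthesis genes 1 was higher, Mvd (1.36 ± 0.31, adjusted p = 0.038), and 2 adjusted over the list alone (camera adjusted p = 0.00242, and adjusted p = 0.625 with an estimated correlation). The list call was lost without the pair of colon replicate 2 libraries (camera adjusted p = 0.0634, median log2 fold change 0.25 against 0.53), and 14 of the 16 were highest of the GFP-high libraries in the one labelled replicate 2. Mvd lost its call without any library but colon GFP-negative replicates 2 and 3 (adjusted p = 0.0503 to 0.132; up to 0.152 over its alternatives). Of 10 regeneration genes 2 were higher and 8 not past (4 adjusted over the list alone; median log2 fold change 2.78, or 1.72 with 1 gene at its bound; camera adjusted p = 0.0025, and adjusted p = 0.292 with an estimated correlation). These were Anxa1, an annexin (346-fold, log2 fold change 8.44 ± 0.77, adjusted p = 0.000798), and Il1rn, the interleukin 1 receptor antagonist (53.1-fold, 5.73 ± 0.89, adjusted p = 0.00814; 4.77 without the library labelled colon GFP-high replicate 2). Of 15 immediate early genes 1 was higher, Nr4a1 (19.1-fold, 4.25 ± 0.64, adjusted p = 0.0068; camera adjusted p = 0.604), and of 12 mucosal defence genes Retnlb alone (1 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.334), whose call was lost without small intestine replicate 1, 2 or 3 (adjusted p up to 0.0694).

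Growth, immune and control lists held no call between colon GFP-high and small intestine with all libraries. Camera placed lower in colon GFP-high the mitosis list (21 of 22 estimates negative, adjusted p = 0.000144, and adjusted p = 0.644 with an estimated correlation), the DNA replication list (18 of 23, 0.0154, and 0.798 with an estimated correlation) and the ribosome biogenesis list (19 of 20, 0.000151, and 0.625 with an estimated correlation). The library labelled colon GFP-high replicate 2 was the lowest GFP-high library for all 22 mitosis, all 23 DNA replication and 15 of 20 ribosome biogenesis genes. Leaving out the pair of colon replicate 2 libraries moved the median log2 fold change of the mitosis list from -0.71 to -0.39 (camera adjusted p = 0.0105) and that of the DNA replication list from -0.73 to -0.44, whose call was lost (0.249). Ube2c had a log2 fold change of -0.68 ± 0.46, Mcm6 -0.91 ± 0.62 and Ncl -1.33 ± 0.78. The MHC class II list was placed lower too (7 of 7 negative, adjusted p = 0.00242, and adjusted p = 0.596 with an estimated correlation), with Cd74 at -3.58 ± 1.71. All 7 genes were highest of the GFP-high libraries in the one labelled replicate 2. Without the pair the median log2 fold change moved from -2.94 to -5.26, and 7 were lower adjusted over the list alone. The camera adjusted p was then 1.45e-05, and 0.456 with an estimated correlation. No other list without a call passed camera, with adjusted p = 0.394 for immune cell (Lyz2 2.01 ± 2.35), 0.578 for stromal cell (Pdgfrb 0.85 ± 0.51), 0.377 for endothelial cell (Esam -1.07 ± 0.52), 0.99 for enteric glia and neuron, 0.604 for red blood cell (Hba-a1 -0.32 ± 1.43), 0.99 for sex-linked (Eif2s3y 0.30 ± 0.22) and 0.863 for mitochondrial RNA (mt-Cytb -0.42 ± 0.43). The median and the camera direction differed in sign for the immune cell and stromal cell lists. Lyz2 turned to -4.78 without the library labelled colon GFP-high replicate 2. It was called lower in edgeR without the pair of colon replicate 2 libraries (-4.78, adjusted p = 0.0391; 1.59e-09 to 0.987 over its alternatives). The immune cell list then had 18 of 19 estimates negative (camera adjusted p = 0.00843, and adjusted p = 0.746 with an estimated correlation).

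Small intestinal cells were compared with colon GFP-negative cells as a secondary comparison. Npy1r was 117-fold lower in small intestine (log2 fold change -6.87 ± 1.17 SE, n = 3, adjusted p = 0.0112 in edgeR) and lower in all 3 libraries, with -7.67 without small intestine replicate 1 and -6.24 without replicate 3. That call was lost with the library name tag as a block (adjusted p = 0.0766, from 6.92e-15 over its alternatives). Lgr5 was 129 ± 75.9 CPM in small intestine and 23.6 ± 33.0 CPM in colon GFP-negative (2.45 ± 1.43, adjusted p = 0.36), with a call without the pair of colon replicate 2 libraries (4.81, adjusted p = 0.0166, from 3.12e-12 to 0.984 over its alternatives). The pair was left out for its Lgr5 values, so this too is no separate test. Nox1 had a log2 fold change of -2.51 ± 0.87 (adjusted p = 0.147), called by DESeq2 (adjusted p = 0.0123, up to 0.522 over its alternatives). In edgeR 1166 genes were called, 352 higher and 814 lower in small intestine, against 2870 in DESeq2 and 1050 in limma-voom, and 895 without the pair of colon replicate 2 libraries. With the library name tag as a block 236 were called, 35 higher and 201 lower (232 of them among the 1166). Small intestinal and colon GFP-negative libraries share only 1 such block, so tag and group overlap. This fall and the lost Npy1r call cannot be told apart from that overlap. The count of 1166 was more than 1.5 times lower without colon GFP-negative replicate 1 (531) or small intestine replicate 1 (706) or 3 (631).

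In the lists, all 11 posterior Hox genes were lower in small intestine than in colon GFP-negative cells (median log2 fold change -9.81, or -6.08 with 5 genes at their bound; camera adjusted p = 3.81e-13, and adjusted p = 0.02 with an estimated correlation). Also lower were 6 of 14 anterior and middle Hox, 12 of 18 goblet cell, 7 of 27 colonocyte and 5 of 8 deep crypt secretory genes. Higher in small intestine were 14 of 21 Paneth cell genes (1 lower), 12 of 25 enterocyte genes, 4 of 30 stem cell genes and 5 of 15 gut regional regulators (1 lower). Without the pair of colon replicate 2 libraries the counts were 10 for stem cell, 4 for enterocyte, 3 for gut regional regulator and 2 for anterior and middle Hox genes. Then 6 of 20 Wnt target genes were higher and 1 lower in small intestine, 3 cholesterol synthesis genes were lower, and no enteroendocrine gene was higher and 2 were lower. Camera called 18 lists, and the posterior Hox call alone held with an estimated correlation, though not without the pair of colon replicate 2 libraries (adjusted p = 0.067 with an estimated correlation). The others called higher in small intestine were stem cell, Wnt target, mitosis, DNA replication, ribosome biogenesis, enterocyte, Paneth cell, regional regulator, Notch and MHC class II. Called lower were colonocyte, goblet, deep crypt secretory, anterior and middle Hox, neuropeptide Y family, cholesterol synthesis and regeneration. These 17 had adjusted p = 0.0728 to 0.641 with an estimated correlation. The MHC class II call was lost without the pair of colon replicate 2 libraries (camera adjusted p = 0.311), and enteroendocrine and immune cell lists were then called lower (0.00531 and 2.76e-07, both with adjusted p = 0.389 with an estimated correlation). The library labelled colon GFP-negative replicate 2 was highest of its group for all 22 mitosis and all 23 DNA replication genes. Among lists with few calls, Gkn3, Olfm4, Fstl1 and Igfbp4 of the stem cell list, Gip, Ghrl and Cck of the enteroendocrine list, Esam and Nos2 were higher in small intestine. Mptx1, Retnlb, Reg4, Spink4 and Kit of the deep crypt secretory list, Gnat3, Mvd, Nr4a1, Anxa1, Il1rn and Ly6a were lower, and all of these genes were chosen after their values were seen. The median or mean and the camera direction differed in sign for 4 uncalled lists, mucosal defence, stromal cell, red blood cell and mitochondrial RNA.

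Genes higher in colon GFP-high than in both other groups were sought because the series title speaks of colon stem cell markers. In edgeR 0 genes met both thresholds, with 16 at an unadjusted p under 0.05 in both contrasts, DESeq2 gave 0 (45) and limma-voom 0 (69). Since 0 genes were called higher than in colon GFP-negative, the overlap and its value from independent lists were both fixed at 0. In 20 simulated draws without effects 0 genes met both thresholds and a mean of 57.4 (73 at most) met both unadjusted. These draws held no difference between the tissues, unlike the data, so no conclusion is drawn from them. Both contrasts share the GFP-high libraries, so part of any overlap may come from them, and 3 libraries are too few to split. Without the pair of colon replicate 2 libraries DESeq2 gave 8 genes (5.93 from independent lists), edgeR 0 (67 at an unadjusted p under 0.05) and limma-voom 0 (212). The 8 genes, chosen after their values were seen, were Rgcc, Bok, Rhov, Sema3f, Ackr3, Ptprt, A930003A15Rik and Gm28723. Rgcc, a regulator of the cell cycle, stood at 293 and 137 CPM in GFP-high replicates 1 and 3 and at 40.0 and 33.6 CPM in GFP-negative replicates 1 and 3. In the replicate 2 libraries labelled GFP-high and GFP-negative it had 29.5 and 235 CPM.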

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

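The fits without the pair of colon replicate 2 libraries, in edgeR, DESeq2 and limma-voom, were chosen only after the result was seen, and the other alternatives were chosen before. The cause of the changes given here was not tested.

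For colon GFP-high against colon GFP-negative edgeR called 0 (226 at an unadjusted p under 0.05, limma-voom 0), DESeq2 1 and, without the pair, DESeq2 700 and limma-voom 2; leaving out single libraries gave 0 to 0. For colon GFP-high versus small intestine the 1173 genes became 2713 in DESeq2, 508 with the replicate block, 437 with the library tag block, 401 at an adjusted p under 0.01 and, without the pair, 508 in edgeR, 1879 in DESeq2 and 603 in limma-voom. Leaving out single libraries gave 564 (without colon GFP-high replicate 2) to 1375 (without colon GFP-negative replicate 3). The other libraries that moved it over 1.5 times were colon GFP-high replicates 1 (705) and 3 (666), colon GFP-negative replicate 1 (683) and small intestine replicates 1 (635) and 3 (566). For small intestine versus colon GFP-negative the 1166 genes became 2870 in DESeq2, 532 with the replicate block, 236 with the tag block, 414 at an adjusted p under 0.01 and 3148 in DESeq2 without the pair. Leaving out single libraries gave 531 (without colon GFP-negative replicate 1) to 1078, with 706 and 631 without small intestine replicates 1 and 3. Genes higher in colon GFP-high than in both other groups numbered 0 in edgeR (16 at an unadjusted p under 0.05), 0 to 0 without single libraries and 8 in DESeq2 without the pair; a fit of only the 2 groups compared does not apply to this count.

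The replicate block assumes that libraries of the same number belong together. Deviations from the group means correlated at -0.762 between the colon replicate 2 libraries, and the other same-number pairs ran from -0.418 to 0.405. These values do not show that the numbers pair the samples. They cannot exclude it either, since exchanged labels in the colon replicate 2 pair would give opposite deviations with or without pairing. The colon GFP-high and GFP-negative libraries of replicate 1 share a name tag, and so do those of replicate 2. Colon GFP-high replicate 3 and small intestine replicate 3 share one too. Small intestine replicate 2, however, carries the tag of the colon replicate 1 libraries. Colon GFP-negative replicate 3 has another tag than the other replicate 3 libraries. Number and tag therefore go together for only some libraries. Under the replicate block the colon contrast changed sign for Nox1 (0.34), Ube2c (0.05), Ncl (0.023), Chga (-0.93) and Fdps (-0.043), and colon against small intestine for Lyz2 (-0.40).

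Camera called 8, 17 and 18 lists in the 3 comparisons, against 0, 1 and 1 with an estimated correlation, 0, 9 and 10 with fry, and 16, 15 and 19 without the pair, of which 0, 1 and 0 held with an estimated correlation. The direction of fry was opposite for NADPH oxidase (adjusted p = 0.973) and mucosal defence (0.973) between the colon fractions. Without the pair the camera direction turned between the colon fractions for mitosis (adjusted p = 1.68e-05, and 0.55 with an estimated correlation), enteroendocrine (7.14e-06, and 0.482 with an estimated correlation), neuropeptide Y family (0.53), BMP response (0.602), mucosal defence (0.207), regeneration (0.101), stromal cell (0.858) and red blood cell (0.117). It also turned between colon GFP-high and small intestine for enteroendocrine (0.146), enteric glia (0.93) and mitochondrial RNA (0.94), and between small intestine and colon GFP-negative for immediate early (0.753) and red blood cell (0.499).

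Among named genes, log2 fold changes between the colon fractions turned sign 96 times over the alternatives, with 594 values neither turned nor moved past the threshold. Without the pair edgeR gave Nox1 1.497, Ube2c 0.59, Ncl 1.36, Chga -4.32, Hoxa7 0.023, Pyy -0.77, Fdps -0.058 and Pdgfrb -0.053. DESeq2 gave Nox1 1.46, Ube2c 0.55, Ncl 1.32, Chga -4.36, Fdps -0.096 and Pdgfrb -0.093, and limma-voom Nox1 1.75, Ube2c 0.61, Ncl 1.18, Chga -4.50, Hoxa7 0.072, Pyy -0.88 and Fdps -0.16. With all libraries limma-voom gave Nox1 0.22, Ncl 0.10, Chga -0.39, Fdps -0.054 and Hba-a1 1.23. The library tag block gave Lgr5 -0.73, Mcm6 -0.33, Agr2 0.28, Chga -0.42, Lrig1 -0.32, Pdgfrb -0.093 and Eif2s3y 0.006. Total-count scaling gave Nox1 0.012, Ube2c 0.20, Ncl 0.16, Hoxa7 0.073, Eif2s3y 0.084 and mt-Cytb 0.076, upper quartile scaling Ube2c 0.086, Ncl 0.024, Hoxa7 0.011 and Eif2s3y 0.035, the filter at 1 CPM Ube2c 0.018 and Ncl 0.009, and RLE and DESeq2 Fdps -0.002 each.

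Leaving out single libraries gave, between the colon fractions, Lgr5 -0.081 to 3.09, Nox1 -0.68 to 1.10, Olfm4 -0.59 to 0.082, Ube2c -0.43 to 0.31, Mcm6 -0.40 to 0.81, Ncl -1.04 to 1.04, Car1 -1.80 to 0.53, Apoa1 -2.40 to 0.32, Agr2 -0.55 to 0.20, Mptx1 -3.11 to 0.089, Chga -3.74 to 1.55, Hoxa7 -0.28 to 0.079, Cdx1 -0.091 to 0.39, Pyy -0.29 to 1.54, Lrig1 -0.17 to 0.99, Cd74 -4.91 to 1.22, Fdps -0.39 to 0.22, Krt7 -0.032 to 0.42, Pdgfrb -0.21 to 0.61, Hba-a1 -2.45 to 0.90, Eif2s3y -0.23 to 0.092 and mt-Cytb -0.32 to 0.029.

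Between colon GFP-high and small intestine 14 values turned, 151 calls were lost and 1013 values held. Rac1 was -0.18, -0.17 and -0.18 without the pair in edgeR, DESeq2 and limma-voom and -0.044 with the tag block. Lyz2 was -4.78, -4.78 and -5.38 without the pair (adjusted p = 0.0391, 1.59e-09 and 0.0292), -1.61 with the tag block and -2.52 in limma-voom. Leaving out single libraries gave Lyz2 -4.78 to 2.61, Rac1 -0.18 to 0.21 and mt-Cytb -0.71 to 0.05. No study gene turned in the secondary comparison, where 61 values held, 4 became calls and 1 call was lost. Depth limits only genes near 3 counts per library, and the spread between libraries limits the rest.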

Other observations

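All tests of patterns in this part, except the splits for colon GFP-high against small intestine and for small intestine against colon GFP-negative, were chosen only after the result was seen.

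Gata5, a transcription factor of the gut endoderm, stood at 71.4 to 80.2 CPM in the 3 small intestinal libraries and at 0 to 1.92 CPM in the 6 colon libraries. Of 25 small intestinal enterocyte genes 23 were lowest of the small intestinal libraries in replicate 2, with Apoa1 at 117 CPM against 14810 and 3732 CPM and Alpi, the brush border alkaline phosphatase, at 20.6 CPM against 1857 and 697 CPM. Krt20, a keratin of mature cells outside that list, was at 55.8 CPM against 2370 and 1009 CPM. The lectin genes Reg3g (4908, 1272 and 444 CPM) and Reg3b (4240, 847 and 298 CPM) descended over small intestinal replicates 1 to 3. Among colon GFP-high libraries Clca1, a goblet cell product, ranged from 14.6 CPM in replicate 1 to 18040 CPM in replicate 2.

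The colon replicate 2 libraries lay against their labels. Of 960 genes chosen in the other 4 colon libraries (370 higher and 590 lower in GFP-high), 97.1% differed the opposite way in this pair, as an exchange of the 2 labels would give. On a scale from GFP-negative to GFP-high in those 4 libraries, the library labelled GFP-high had a median position of 0.148 and the one labelled GFP-negative 0.955. The difference was 0.807 (bootstrap 0.780 to 0.841, no measure of the spread between samples, since there is 1 such pair). A poor separation in the sort would leave both at a similar position. Exchanged labels may therefore explain the pattern, as a hypothesis found and tested on the same data. No biological explanation was tested, and the labels were kept.

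Immune transcripts were high in colon GFP-negative replicate 3. Of 18 abundant leukocyte transcripts outside the lists, 17 were highest there, with Ighm, the heavy chain of IgM, at 555 CPM, and the exception was Ptpn6 (153 CPM against 185 CPM in small intestine replicate 3). Ighm was 11.8 CPM in colon GFP-negative replicate 1 and 11.5 CPM in the library labelled colon GFP-high replicate 2. It was 0 and 0.324 CPM in colon GFP-high replicates 1 and 3 and 0.0198 CPM in the library labelled colon GFP-negative replicate 2. The median of all genes against the other GFP-negative libraries was -0.077 (log2), against 7.28 for the 19 immune cell genes. The immune median was 4.59 against replicate 1 alone and 10.62 against the library labelled replicate 2 alone, with -0.065 and -0.087 for all genes. TMM scaling itself keeps the median of all genes near 0, so that median alone tests nothing. A scaling factor moves all genes alike, so the gap between the immune genes and all genes argues against a scaling effect. Immune cells in the sorted fraction may explain the pattern, since no epithelial surface marker is named for the sort. No biological explanation was tested.

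Tuft cell genes were high in replicate 3 of both colon GFP-high and small intestine, with 10 of 16 highest in replicate 3 of both groups. The median tuft gene stood above the median of all genes by at least 1.40 (log2), which argues against scaling. It stood above the median enteroendocrine gene by at least 2.44. In small intestine this argues against a higher yield of rare secretory cells in general. In the colon it cannot, since the reference held the library labelled GFP-high replicate 2, highest of its group for 22 of 25 enteroendocrine genes. The replicate 3 libraries of colon GFP-high and small intestine share a name tag that the labels do not explain. Their deviations outside the tuft list correlated at 0.278, against up to 0.523 among 19 pairs of other groups and tag starts, so a shared day or animal cannot be told apart from other causes, and no tag holds enough libraries for a comparison within it. No biological explanation was tested.

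Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. For colon GFP-high against colon GFP-negative the real split called 0 genes in edgeR (226 at an unadjusted p under 0.05, DESeq2 1, limma-voom 0), a count that all 10 splits reach whatever the data, and the highest other called 26. That split set colon GFP-high replicates 1 and 3 with the library labelled colon GFP-negative replicate 2, which points to a structure of the samples. It is the grouping that exchanged labels in the colon replicate 2 pair would give, with 2857 genes at an unadjusted p under 0.05. It rests on the same libraries as the pattern above, so it is no separate test of an exchange. For colon GFP-high against small intestine the real split called 1173 genes and the highest other 0, and for small intestine against colon GFP-negative 1166 and 0, so that 1 of the 10 splits reached the real count in each. For genes higher in colon GFP-high than in both other groups the real count was 0 in edgeR (16 at an unadjusted p under 0.05 in both contrasts, DESeq2 0, limma-voom 0), which all 100 splits drawn reach whatever the data, so this count of splits tests nothing. The highest other count, 446, came from the split with the 3 small intestinal libraries as the first group, which follows the structure of the samples.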
